A study of Homo sapiens with 3 samples.

How the data were processed

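RNA from HEK293 cells, an established human embryonic kidney line, was sequenced in 3 libraries with 1 library per group. All 3 cultures received troglitazone, a synthetic agonist of the nuclear receptor PPARG. The Control library came from cells labelled with the drug and no over-expressed gene, the PPARG library from cells that also over-expressed PPARG from a plasmid, and the PPARG+PPARGD5 library from cells that co-expressed PPARG and its isoform PPARGD5 from plasmids. Per the labels' protocols, plasmids were delivered by lipid transfection, and paired-end libraries were made with a strand-specific kit. The labels do not describe whether the Control cells received a plasmid or the transfection reagent.

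The deposited table held 1 column per library and 14170 genes named by symbol. Its values are a signal scale: per the labels they are normalised read counts, and per the file name the authors scaled them by the upper quartile. The values were not whole numbers. Per the submitters' processing notes, FastQC, TopHat2 2.0.10, SAMtools and bedtools were used with the builds GRCh37 and hg19. The role of each tool, the gene annotation, the strand setting of the counting and the gene filter are not given in the sources used here. No per-sample column of the table was left out.

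Depth was read only approximately from the table. Low values fell into bands, as values made from whole reads would, but values inside a band differed from gene to gene, so exact read counts were not recovered and no counting interval is given. In the PPARG+PPARGD5 library 10 bands below a value of 22 were spaced by about 2.4. Within 5 narrow ranges of that library's values, the spacing in the other libraries was estimated with a periodogram. Its median was about 4.2 in the Control library, where the estimates ran from 4.2 to 8, and about 0.45 in the PPARG library, where they ran from 0.34 to 0.47. With these spacings the table held about 1800000 reads for Control, 14000000 for PPARG and 3100000 for PPARG+PPARGD5. A value equal to the expression filter then stood for about 48 reads in Control, 450 in PPARG and 86 in PPARG+PPARGD5. The filter acts on the mean over the 3 libraries, so a tested gene can have fewer reads in a single library.

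Log2 ratios were computed as log2(value + 53.5) differences between libraries. The pseudocount was the lower quartile of the non-zero values, and ratios of low genes are understated on this scale. A gene was tested for size when its mean over the 3 libraries was at least 202.6, the median of the gene means, which left 7085 genes. A gene counted as different when its ratio was at least 2-fold. With 1 library per group there is no replicate check, so no difference was tested statistically and no p-value is given. Every ratio compares libraries, not conditions.

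Before the data were examined, 35 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The rule names PPARG, the 8 highest and the 8 lowest tested genes of each comparison, up to 3 tested members with the ratio of largest size in each list described, and 6 genes that differ in PPARG and return in PPARG+PPARGD5. The last were at least 2-fold different in PPARG against Control and in the opposite direction in PPARG+PPARGD5 against PPARG, and were ranked by the smaller of these log2 ratios in size. Other genes are stated to have been chosen after their values were seen. Some genes that the rule names are not reported here. For each list with at least 3 tested members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean value in 20 bins. A percentile of at most 2.5 or at least 97.5 is described as standing apart. This percentile describes the libraries and is not a test of the conditions.

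Gene positions, strand, transcript length and GC content were taken from GENCODE release 29 on GRCh38, which is not the build the authors used. Symbols were matched for 13478 of 14170 genes, 95.1%, of which 11 were matched through an older symbol. Of the tested genes, 6779 were matched. A gene was said to have an opposite-strand partner when its exons overlapped exons of another gene of the table on the other strand. After the data were examined, counts and list medians were also computed for the 5117 tested genes without such a partner, for the 1318 tested genes with no annotated opposite-strand gene within 5000 bases, and for the 5117 genes after subtracting medians over 20 bins of GC content and then of transcript length, in 2 passes.

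For the overlap of comparisons that share the Control library, and for genes that return towards Control, 20 sets of unchanged libraries were simulated with counting noise at the estimated depths. A second simulation added a log2 spread of 0.28 per library, chosen so that the spread of ratios matched that of PPARG+PPARGD5 against Control. After the data were examined, the overlap was also counted in the simulation for as many of the most extreme genes as had been observed, because few simulated genes passed the 2-fold limit. Another simulation was added as well, with a log2 spread of 0.50 in the PPARG library, so that the robust SD of PPARG against Control matched, at 0.538 simulated and 0.537 observed. It was 0.380 with equal spread. The added simulation gave 0.516 for PPARG+PPARGD5 against PPARG, below the observed 0.645. The calculations were tested on simulated data of 14170 genes at these depths. In PPARG against Control, all 50 genes planted 3-fold higher were recovered, as were the 35 genes planted 3-fold lower that passed the filter. In PPARG+PPARGD5 against Control, all 25 genes planted 3-fold higher were recovered, as were 13 of the 14 genes planted 3-fold lower that passed the filter. Alternatives fixed beforehand were median-of-ratios scaling, equal totals, a pseudocount 10 times smaller and 5 times larger, no filter, a stricter filter at the upper quartile of the gene means, and fold limits of 1.5 and 4. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.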

Results

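Gene expression was measured by RNA sequencing in troglitazone-treated HEK293 cells, with 1 library from drug-treated Control cells, 1 from cells over-expressing PPARG and 1 from cells co-expressing PPARG and PPARGD5. PPARG is a nuclear receptor that drives adipocyte differentiation and lipid storage, and PPARGD5 is an isoform of it that lacks the ligand-binding domain. The normalised counts summed to 7468095 in Control, 6447087 in PPARG and 7371384 in PPARG+PPARGD5. The low values put the depth at about 1800000, 14000000 and 3100000 reads in this order, so counting error is largest in Control. There is no replicate check for any difference below.

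The over-expressed gene was examined first. PPARG, annotated on chromosome 3 from 12287368 to 12434356 on the plus strand in GENCODE release 29 (GRCh38), had a normalised count of 123.3 in Control, 20420 in PPARG and 52915 in PPARG+PPARGD5. The log2 ratios were 6.86 for PPARG against Control, 8.23 for PPARG+PPARGD5 against Control and 1.37 for PPARG+PPARGD5 against PPARG. Gene-level counts do not separate the isoforms, nor plasmid transcripts from chromosomal ones.

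The first comparison asked which genes differ when PPARG is over-expressed in the presence of its agonist. Genes of the integrated stress response, in which ATF4 induces amino acid synthesis and stress regulators, were higher in the PPARG library. ATF3, a stress-induced transcription factor, had counts of 286.4 in Control and 1550 in PPARG, a log2 ratio of 2.24. The asparagine synthetase gene ASNS was higher by a log2 ratio of 1.74, and PSAT1, an enzyme of serine synthesis, by 1.51. The list had a median log2 ratio of 0.80 over 19 tested members, of which 7 were at least 2-fold higher and 1 at least 2-fold lower. Its percentile among matched lists was 100. The 1 lower member, DDIT3, the CHOP transcription factor, had a log2 ratio of -1.38 and overlaps MARS on the opposite strand.

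Targets of p53 were also higher in PPARG than matched lists, with a median of 0.34 over 14 members and a percentile of 98.3. PMAIP1, which encodes the pro-apoptotic protein NOXA, had 823.8 in Control and 2887 in PPARG, and the growth arrest gene GADD45A had a log2 ratio of 1.16. The oxidative stress list had a median of 0.24 at a percentile of 98.2, with the haem oxygenase gene HMOX1 at 1.01. With the stricter filter its median was -0.30. The calls for both lists depended on the gene set. The percentiles of p53 targets and oxidative stress were 94.6 and 95.7 without overlapping genes, 94.4 and 97.3 without the expression filter, and 99.3 and 78.9 after correction for GC content and length, so that p53 targets stood apart again after the correction. Common reference genes stood apart as well, at a median of 0.25 and a percentile of 99.9, with B2M at 1.29, or 0.96 after the correction, and HPRT1 at 0.92. The remaining genes among the 8 highest were CREB5, a transcription factor of the CREB family, at 2.11, LOC100132247 at 2.03, the atypical kinase gene RIOK3 at 1.72 and the Golgi GTPase gene ARF4 at 1.60.

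Lipid genes known as PPAR targets did not stand apart in the PPARG library. Of 33 listed genes for lipid uptake, storage and lipolysis, 25 were in the table and 8 were tested, with a median of -0.30 and a percentile of 5.31. The members that were at least 2-fold lower, CIDEB at -3.06 and DGAT1 at -1.41, overlap NOP9 and HSF1 on the opposite strand. The 15 tested genes of fatty acid oxidation had a median of 0.01 at a percentile of 53.6, and 0 of them were 2-fold different. Without the expression filter, 12 of 25 lipid uptake members lay above 0, with a median of -0.015 at a percentile of 26.7, and 20 of 29 members of fatty acid oxidation, with a median of 0.14 at a percentile of 88.7. Some classical targets below the filter were chosen after their values were seen. Their low values in Control correspond to few reads, at about 4.2 per read. PDK4, a kinase that restrains glucose oxidation, had counts of 25.8 in Control, 77.8 in PPARG and 69.0 in PPARG+PPARGD5. The lipoprotein lipase gene LPL had 26.0, 79.9 and 53.9 in the same order, and ANGPTL4, an inhibitor of that enzyme, had 31.8, 2.78 and 22.9. The fatty acid import gene CPT1A had 112.9, 168.8 and 120.8.

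Across the 7085 tested genes, 135 were at least 2-fold higher and 452 at least 2-fold lower in PPARG than in Control. The 8 lowest genes were SYNC (-3.45), ATP6V1C2 (-3.42), LOC100996485 (-3.39), ZACN (-3.34), ENTPD1 (-3.32), CAPN12 (-3.32), SPRN (-3.24) and RUSC1-AS1 (-3.23). Of these 8 genes, 7 were matched to the annotation and 6 have an opposite-strand exon partner, such as RBBP4 for SYNC and PDIA6 for ATP6V1C2. Such partners were present for 68.4% of the matched lower genes, against 11.8% of the higher and 21.8% of the other genes. The values of these overlapping genes are therefore uncertain. Across the 5117 genes without a partner, which are not independent replicates, the ratio also followed transcript GC content, with a Spearman correlation of -0.53. Of these genes, 112 were higher and 135 lower. After correction for GC content and transcript length as well, 63 were higher and 106 lower. Scaling to equal totals, which shifts the median ratio of the tested genes by 0.19, gave 352 higher and 318 lower genes.

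**Figure D1:**
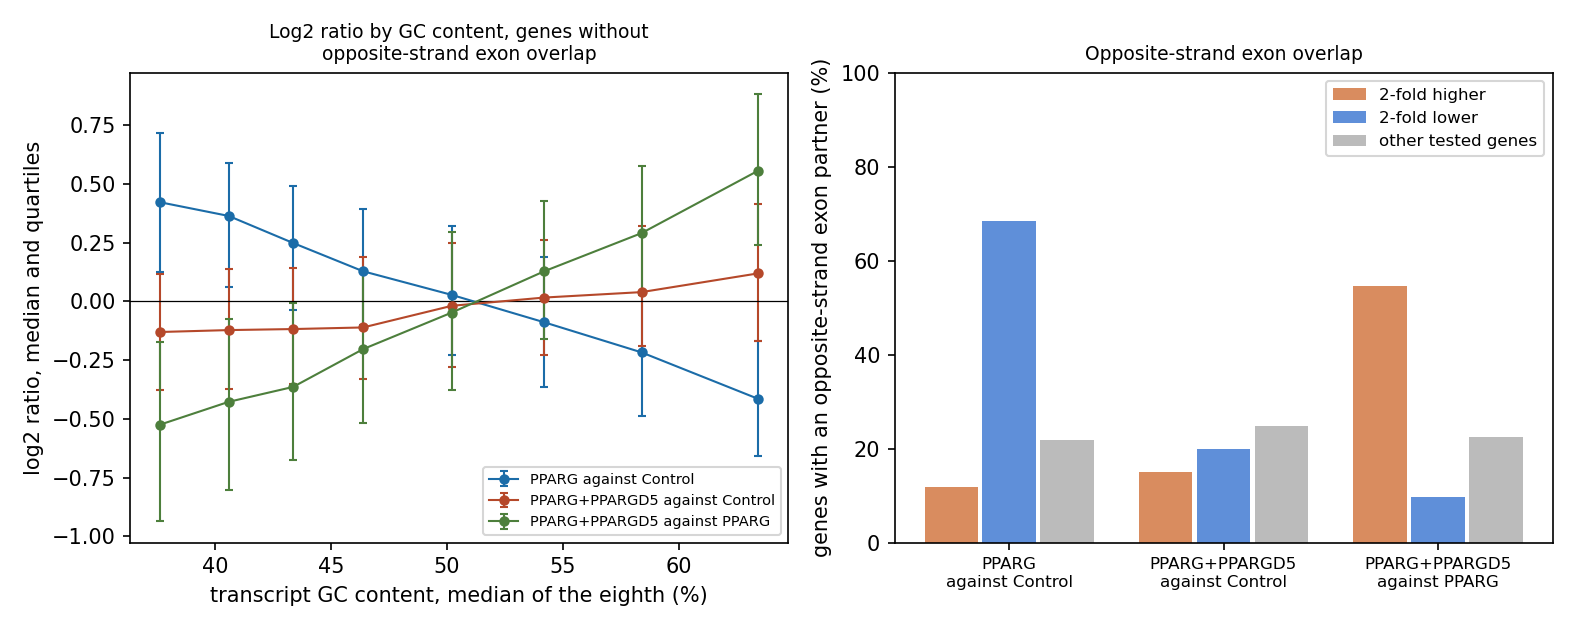
Left, median log2 ratio with quartiles (vertical axis) over eighths of the genes without opposite-strand exon overlap, by transcript GC content in percent (horizontal axis), for the 3 comparisons. The medians run from 0.42 to -0.42 for PPARG against Control and from -0.52 to 0.56 for PPARG+PPARGD5 against PPARG. Right, percent of matched genes with an opposite-strand exon partner, which is 68.4% for genes lower in PPARG than in Control and 54.5% for genes higher in PPARG+PPARGD5 than in PPARG.

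The second comparison set the co-expressing cells against Control. Stress-response and immediate early genes were higher in PPARG+PPARGD5. ATF3 had a count of 5394, a log2 ratio of 4.002 and the largest after PPARG itself. PPP1R15A, a phosphatase subunit that restores translation after stress, followed at 2.94, PHF21B at 2.54 and GADD45A at 2.42. ARC, an activity-induced gene, was at 2.38, the GADD45 family gene GADD45B at 2.11 and TRIB3, a pseudokinase induced by ATF4, at 1.93. In Control, PHF21B, ARC and TRIB3 had counts of 42.6, 56.7 and 101.3, which correspond to few reads. All 19 tested members of the integrated stress response list lay above 0, 8 of them at least 2-fold, with a median of 0.92 and a percentile of 100. All 12 tested immediate early genes lay above 0, 4 of them at least 2-fold, with a median of 0.72 and a percentile of 100. In this list the transcription factor gene JUN was at 1.82 and DUSP1, a MAP kinase phosphatase, at 1.85. The lists share members, among them ATF3. Without members shared with any other list, the medians were 0.74 and 0.70. Histone genes and small structural RNAs, a list that follows how RNA was selected, were higher alongside them. Read without the expression filter, this list had a median of 0.55 over 15 members at a percentile of 100, with 14 members above 0.

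Further lists lay above matched lists in PPARG+PPARGD5 against Control. Adipogenic transcription factors and regulators had a median of 0.56 over 18 members at a percentile of 100, with KLF6 at 1.27, the transcriptional repressor HES1 at 1.15 and GATA2 at 1.06. Of these members 14 lay above 0 and 4 below, among them CEBPA at -0.11. The 4 tested adipocyte markers did not stand apart, with a median of -0.10 at a percentile of 37.7. The rise of the regulator list is therefore not read as adipocyte differentiation. NOTCH targets had a median of 0.46 over 7 members at a percentile of 99.3, with HEY2 at 1.20. The p53 targets had a median of 0.39 at a percentile of 99.9, with SESN2 at 1.41 and the pro-apoptotic gene BBC3 at 1.32. Of their 14 members, 11 lay above 0 and 3 below, among them MDM2 at -0.10, which overlaps CPM on the opposite strand. SESN2 is also in the stress-response list, and the median of the 12 members in no other list was 0.32. Hypoxia genes had a median of 0.37 at a percentile of 99.3, with the angiogenic factor VEGFA at 1.09 and the collagen cross-linking enzyme LOX at -1.07. Without the expression filter the hypoxia list was at a percentile of 80.8.

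Genes of lipid synthesis were lower in PPARG+PPARGD5 than in Control. All 13 tested genes of fatty acid synthesis lay below 0, with a median of -0.46 and a percentile of 0.06. ACLY, which supplies cytosolic acetyl-CoA, was at -0.82, the elongase ELOVL6 at -0.71 and the fatty acid synthase gene FASN at -0.62. Cholesterol synthesis had a median of -0.37 over 18 members at a percentile of 0.09. Glycolysis had a median of -0.33 at a percentile of 0.40, with LDHA at -0.59, and heat shock genes had a median of -0.37 at a percentile of 0.16, which was 3.38 without overlapping genes and 1.02 with the correction as well. In the heat shock list the chaperone gene HSPA1A, which has a near-identical copy and is therefore uncertain, was at -1.60, while BAG3, one of its co-chaperones, was at 1.13. No gene of fatty acid synthesis, cholesterol synthesis or glycolysis was 2-fold different. The PPAR targets in lipid uptake had a median of -0.34 at a percentile of 2.79, and those in fatty acid oxidation a median of -0.05 at a percentile of 44.2.

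In all, 143 genes were at least 2-fold higher and 52 at least 2-fold lower in PPARG+PPARGD5 than in Control. The 8 lowest were the matrix proteoglycan gene VCAN (-1.70), the insulin receptor substrate gene IRS4 (-1.62), HSPA1A, the receptor phosphatase gene PTPRG (-1.44), BRWD3 (-1.39), ASB16 (-1.38), GNPTAB (-1.31) and VPS13A (-1.31). None of the 8 highest or the 8 lowest genes has an opposite-strand exon partner in the table. Such partners were present for 15% of the higher, 20% of the lower and 24.8% of the other matched genes. Trends with transcript properties were present here too. Across the 5117 genes without a partner, the ratio had Spearman correlations of 0.21 with GC content and -0.27 with transcript length. The matched higher genes had medians of 56.0% GC and 2770 bases, and the matched lower genes 43.6% and 6274 bases. With correction and without overlapping genes, 96 were higher and 32 lower. Of the genes named in this comparison, GATA2 at 0.94, VEGFA at 0.97, BAG3 at 0.96 and VPS13A at -0.999 were then no longer 2-fold different.

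**Figure D2:**
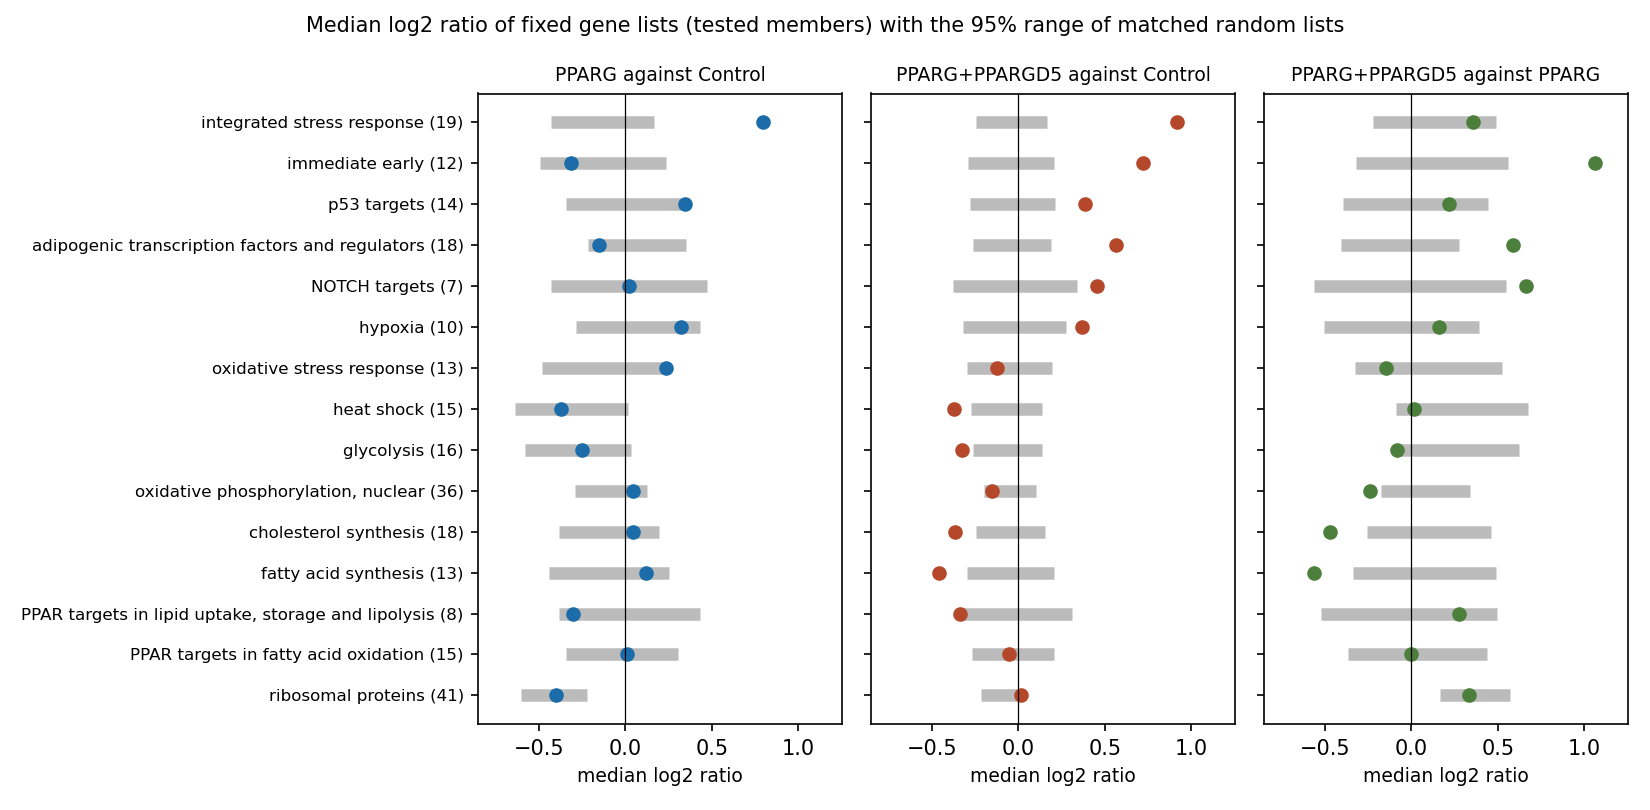
Median log2 ratio (horizontal axis) of 15 fixed gene lists (vertical axis, tested members in brackets) in the 3 comparisons. Points are list medians and grey bars the central 95% of medians of 10000 random lists matched on mean value. The integrated stress response list lies at 0.80 and 0.92 in the comparisons against Control, and fatty acid synthesis lies at -0.46 and -0.56 in the comparisons of PPARG+PPARGD5.

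The third comparison asked how the co-expressing cells differ from cells with PPARG alone. Immediate early genes were higher in PPARG+PPARGD5, with a median of 1.06 over 12 members, all above 0 and 7 at least 2-fold higher, at a percentile of 100. JUN had counts of 4022 in PPARG and 16856 in PPARG+PPARGD5, a log2 ratio of 2.05, and IER2 was at 1.70. After correction for GC content and length they were at 1.69 and 1.13. The histone and small structural RNA list, again without the filter, was higher as well, with a median of 0.43 at a percentile of 99.95 and all 15 members above 0. Its 2 tested members, HIST1H1C and HIST1H2BK, were at 1.23 and 0.70, but at 0.75 and 0.08 after correction for GC content and length. With so few tested members no corrected list median is given, and part of this rise may follow those trends. The blood cell marker list was higher too. Its 4 members in the table, CD14, CD68, LYZ and SPI1, all lay below the filter and had log2 ratios above 0, with a median of 0.51 at a percentile of 99.5. These low values were not corrected for GC content and length, so this rise too may follow those trends. In the stress-response list, ATF3 was at 1.76 and PPP1R15A at 1.61, or 1.60 and 1.18 after the correction. DDIT3 was at 2.30, but it overlaps MARS on the opposite strand, so its value is uncertain. The list median of 0.36 lay within the range of matched lists at a percentile of 88.5. This percentile was 98.4 without overlapping genes and 79.1 with the correction as well, and the median of the 13 members in no other list was 0.07. NOTCH targets had a median of 0.66 at a percentile of 98.97, with HES4 at 1.59, or 0.69 after correction for GC content and length, and HES1 at 1.31. The adipogenic regulators had a median of 0.59 at a percentile of 99.96, but 7 of the 18 members are in other lists, and the median of the remaining 11 was 0.11. After the correction, without overlapping genes, the whole list had a median of 0.11 at a percentile of 93.7.

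Genes of lipid synthesis were lower in PPARG+PPARGD5 than in PPARG. Fatty acid synthesis had a median of -0.56 over 13 members at a percentile of 0.13, with 12 members below 0. Its 2 members that were at least 2-fold lower were the elongase ELOVL5 at -1.26 and the desaturase SCD at -1.16. Cholesterol synthesis had a median of -0.47 at a percentile of 0.12, with the squalene epoxidase gene SQLE at -1.13, CYP51A1 at -0.96 and SC5D at -0.92. Of its 18 members 13 lay below 0 and 5 above, and only SQLE was at least 2-fold lower. Nuclear genes of oxidative phosphorylation had a median of -0.24 over 36 members at a percentile of 0.82, which was 3.22 without overlapping genes and 0.20 with the correction as well, with SDHC, a subunit of succinate dehydrogenase, at -1.14. After the correction these medians were -0.51, -0.60 and -0.35. The 8 lowest genes were PTAR1 (-2.002), the transferrin receptor gene TFRC (-1.76), UHMK1 (-1.72), the integrin gene ITGAV (-1.67), EPT1 (-1.64), PTBP3 (-1.61), ATP13A3 (-1.61) and RICTOR (-1.61), an mTOR complex component that overlaps OSMR on the opposite strand. After the correction SDHC was at -0.61, SCD at -0.96, PTBP3 at -0.97 and ATP13A3 at -0.97, below 2-fold, while UHMK1 was at -1.14 and ITGAV at -1.03.

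In this comparison 598 genes were at least 2-fold higher and 344 at least 2-fold lower in PPARG+PPARGD5. The 8 highest were TMEM184A (3.17), CAPN12 (3.07), CNTD1 (3.03), PTGDR2 (3.02), SLC25A35 (2.95), MXD3 (2.95), CCDC42B (2.92) and SNX22 (2.89). All 7 of these genes that were matched to the annotation have an opposite-strand exon partner. SNX22, on chromosome 15 from 64151715 to 64157481 on the plus strand, overlaps PPIB, and MXD3 overlaps PRELID1. Partners were present for 54.5% of the higher, 9.70% of the lower and 22.4% of the other matched genes. Without overlapping genes 260 were higher and 298 lower, and with the correction for GC content and length 138 were higher and 68 lower. Scaling to equal totals, which shifts the median ratio of the tested genes by -0.17, gave 418 higher and 648 lower genes.

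**Figure D3:**
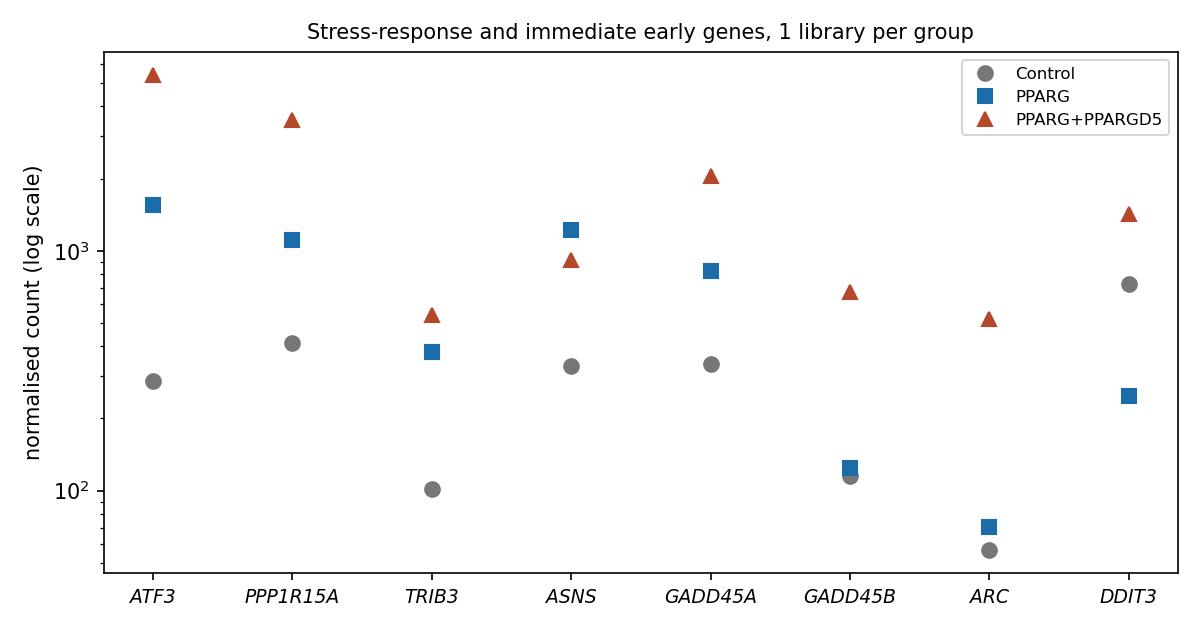
Normalised counts on a log scale (vertical axis) of 8 stress-response and immediate early genes (horizontal axis) in the Control (circles), PPARG (squares) and PPARG+PPARGD5 (triangles) libraries, 1 library each. ATF3 lies at 286.4, 1550 and 5394, while GADD45B lies at 114.9, 123.8 and 672.6, and DDIT3, which overlaps another gene on the opposite strand, is lowest in PPARG.

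The comparisons against Control had 28 genes at least 2-fold higher in both, among them ATF3, CREB5, RIOK3, ASNS, PMAIP1, GADD45A, PPP1R15A, TRIB3, KLF6 and HMOX1. Independent lists of these sizes would share 2.72 genes, while the most extreme genes of simulated unchanged libraries with the extra spread, taken at the same list sizes, shared 26.8. They shared 14.9 with a larger spread in the PPARG library and 61.2 with counting noise only. Of the lower genes, 9 were shared, against 3.32 for independent lists and 23.4, 16.1 and 41.0 in these simulations. Without overlapping genes and after the correction, 25 higher genes were shared, against 1.18 for independent lists and 12.9, 7.70 and 33.5 simulated at those sizes. The 4 lower genes shared in that set compare with 0.663 for independent lists and 8, 4.65 and 17.1 simulated. The simulated ratios were not corrected. The corrected set had a robust SD of 0.387 in PPARG against Control, beside 0.380 simulated with equal and 0.538 with larger spread. The larger spread, which gave 7.70 and 4.65, therefore does not match that set. The simulated number depends on the spread assumed, and part of the shared genes may come from the shared Control library, which cannot be split. Across the tested genes, which are not independent replicates, the ratios had a Pearson correlation of 0.24 and a covariance of 0.07, beside correlations of 0.53 and 0.38 with a covariance of 0.08 in the simulations with equal and larger spread, and 0.76 and 0.01 with counting noise only. Without overlapping genes and after the correction they were 0.40 and 0.08.

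Genes that differed in PPARG lay mostly closer to Control in PPARG+PPARGD5. This held for 117 of the 135 higher genes (86.7%) and 449 of the 452 lower genes (99.3%), and 94.2% and 94.3% of such genes did so in the simulation with equal extra spread, where they averaged 32.7 higher and 24.4 lower genes. That simulation understates the spread of PPARG against Control. With a larger spread in the PPARG library 99.2% and 98.5% did so, of an average of 253 higher and 186 lower genes. The median share of the log2 ratio that was kept was 0.24 for higher and 0.13 for lower genes, beside 0.55 for both with equal spread and 0.27 and 0.29 with the larger spread. A return of at least 2-fold was seen for 57 of the 135 higher genes (42.2%) and 350 of the 452 lower genes (77.4%), and in the simulations for 7.49% and 5.94% of such genes with equal spread and 39.4% and 33.2% with the larger spread. After the correction and without overlapping genes it was seen for 12 of 63 higher genes (19.1%) and 69 of 106 lower genes (65.1%). The simulations hold no offset tied to opposite-strand overlap or GC content, and 169 of the observed lower genes were at least 4-fold lower. These simulations therefore cannot tell a return caused by PPARGD5 from a difference of the PPARG library. Ranked by whichever was smaller in size, the log2 ratio of PPARG against Control or that of PPARG+PPARGD5 against PPARG, the leading 6 genes were CAPN12, CNTD1, SLC25A35, MXD3, CCDC42B and SNX22, of which the 5 matched ones overlap an opposite-strand gene. In the corrected set without overlapping genes, 43 of 63 higher and 106 of 106 lower genes lay closer to Control, and the shares kept were 0.59 and 0.13. Among the 381 tested members of the fixed lists other than PPARG, which were not selected on these libraries, 191 (50.1%) lay closer to Control in PPARG+PPARGD5 than in PPARG, against 41.1%, 50.8% and 61.9% in the simulations with no extra spread, equal extra spread and a larger spread in PPARG.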

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

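Alternatives on overlapping genes, GC content and length were chosen after the data were examined; the others were fixed before. The cause of each move was not tested, except that a filter or a limit by its construction tests fewer or more genes. In PPARG against Control the 135 higher genes became 352 with equal totals, 237 and 15 with the smaller and larger pseudocount, 244 with no filter, 37 with the stricter filter, and 833 and 4 with fold limits of 1.5 and 4. The 452 lower genes became 278 with the larger pseudocount, and 1144 and 169 with those limits. Without overlapping genes 135 were lower. With no opposite-strand gene within 5000 bases 38 were higher and 25 lower, and after correction for GC content and length 63 and 106.

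In PPARG+PPARGD5 against Control the 143 higher genes became 41 with the larger pseudocount, 259 with no filter, 56 with the stricter filter, and 565 and 7 with the fold limits. The 52 lower genes became 105 and 3 with the smaller and larger pseudocount, 21 with the stricter filter, and 519 and 0 with the limits. With no opposite-strand gene nearby 45 were higher and 8 lower, and after correction 32 were lower. In PPARG+PPARGD5 against PPARG the 598 higher genes became 322 with the larger pseudocount, 1366 and 125 with the limits, 260 without overlapping genes, 60 with no opposite-strand gene nearby and 138 after correction. The 344 lower genes became 648 with equal totals, 45 with the larger pseudocount, 123 with the stricter filter, 1199 and 1 with the limits, 96 with no opposite-strand gene nearby and 68 after correction.

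The PPARG ratio was 5.73 in PPARG against Control with the larger pseudocount, and 8.69 and 7.09 in PPARG+PPARGD5 against Control with the smaller and larger one. Genes higher in PPARG lay closer to Control with PPARGD5 in 92.9% of cases with equal totals, 78.4% with the stricter filter and 68.2% after correction. For lower genes the share was 100% with the larger pseudocount, the stricter filter and the correction. Genes higher in both comparisons against Control numbered 44 and 5 with the smaller and larger pseudocount and 11 with the stricter filter. Genes lower in both numbered 0 with the larger pseudocount, 19 with no filter, 2 with the stricter filter and 4 without overlapping genes. Of 618 list medians under the alternatives, 603 moved by less than the spread of matched lists. The sign changed in 53, of which 1 had stood apart from matched lists, the oxidative stress list in PPARG against Control, at -0.30 with the stricter filter. Of 231 list percentiles without the filter, without overlapping genes or after correction, 9 ceased to stand apart, as given with each list, and 9 came to do so. In PPARG against Control these were matrix genes at 1.23 with no filter and hypoxia at 97.8 after correction, and in PPARG+PPARGD5 against Control mitosis at 0.77 after correction. In PPARG+PPARGD5 against PPARG they were PPAR cofactors at 1.02 and p53 targets at 98.5 with no filter, p53 targets at 99.1 and the stress response at 98.4 without overlapping genes, and glycolysis at 0.20 and reference genes at 1.24 after correction. Of 1368 ratios of named genes, 1309 moved by less than the spread of ratios. The sign changed in 12, and in 0 of those that were at least 2-fold. Depth limits Control most, where a value equal to the filter stands for about 48 reads. Tested genes can have fewer reads there, because the filter acts on the mean over the 3 libraries.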

Other observations

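Interferon-response genes had too few tested members for a percentile, so the list was read without the expression filter. Its 24 members in the table had a median log2 ratio of 0.22 in PPARG against Control at a percentile of 98.95, and 0.13 in PPARG+PPARGD5 against Control at a percentile of 88.6. These medians were not corrected for GC content, which the ratio followed in PPARG against Control. Single members, chosen after their values were seen, were far apart between the libraries. IFIT2, an interferon-induced antiviral gene, had normalised counts of 12.6 in Control, 195.7 in PPARG and 373.2 in PPARG+PPARGD5, although it overlaps LIPA on the opposite strand. The ubiquitin-like modifier ISG15 had 34.8, 119.9 and 390.4 in this order, IFIT3 had 19.7, 102.7 and 163.2, and OASL had 3.10, 48.3 and 78.4. The low values in Control correspond to few reads.

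Histone genes and small structural RNAs, which were higher in PPARG+PPARGD5 than in both other libraries, had a median of -0.06 in PPARG against Control without the filter, at a percentile of 21.9. The linker histone gene HIST1H1C had 223.3, 190.3 and 517.4. The epithelial list, with 4 tested members, had a median of -0.79 in PPARG against Control at a percentile of 1.47; its members KRT8 and KRT18 overlap each other on opposite strands. SERPINB9, a granzyme B inhibitor chosen after its values were seen, had no opposite-strand partner and counts of 207.3, 56.4 and 590.8.

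The tests on opposite-strand shares, on the trend with GC content in PPARG+PPARGD5 against Control and on interferon genes were chosen only after the result was seen. The first pattern is the set of 452 genes lower in PPARG than in Control. Counting noise in Control would gather them among low genes, but their median mean value was 1.62 times that of the other tested genes (1.47 to 1.83 over 2000 resamplings of genes). That mean includes the Control value, which selection on a low ratio tends to raise. In simulated unchanged libraries with counting noise only, 0 genes were at least 2-fold lower in PPARG against Control. Reads from opposite-strand genes, counted in Control and PPARG+PPARGD5 but not in PPARG, are a candidate cause for the 292 genes with a partner. The share of genes with one was 46.8 percentage points higher than among other genes. Across 1662 genes with a partner the ratio had a Spearman correlation of -0.25 with the level of the partner. Across the 5117 genes without one, however, it had a correlation of -0.29 with the gene's own mean value. Whether the -0.25 goes beyond such a trend with level was not tested, so it does not single out opposite-strand reads. For the 135 matched genes without a partner, repression by PPARG stays open, since their median ratio in PPARG+PPARGD5 against Control was -0.23, between the bounds set beforehand, and PPARGD5 could also have restored them. Opposite-strand reads stay open for part of these genes as well, because only exon overlap with genes of the table counted as a partner. Lower genes made up 77% of the changed genes and 54.7% of those without a partner. With no annotated opposite-strand gene within 5000 bases they made up 39.7%, with 25 lower and 38 higher genes.

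The second pattern is the trend with GC content, with a Spearman correlation across genes of -0.53 in PPARG against Control. A GC-dependent difference of the PPARG library as a whole may account for it. In that comparison 233 members of lists unrelated to lipids had a correlation of -0.39. They were measured in the same libraries, and a broad effect of PPARG could give such a value too. This value therefore cannot tell a library difference from such an effect. A change of GC-rich transcripts caused by PPARG in both libraries that over-express it is argued against by the correlation of 0.21, with the other sign, in PPARG+PPARGD5 against Control. A change that PPARGD5 reversed stays open, because it coincides with the library.

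The third pattern is the higher level of stress-response genes in PPARG+PPARGD5 against Control. The trends with GC content and length are argued against by a median of 0.95 after both were removed, at a percentile of 100, and opposite-strand reads by a median of 0.99 without overlapping genes. Plasmid transfection rather than the encoded proteins stays open. The interferon list, which responds to foreign nucleic acid, had a median of 0.22 in PPARG against Control at a percentile of 98.95, but of 0.13 in PPARG+PPARGD5 against Control, where at a percentile of 88.6 it did not stand apart. Its mean log2 ratios were 0.32 and 0.47 in this order, with 2 and 5 of the 24 members at least 2-fold higher. Only 2 members passed the filter, so these values were not corrected for GC content. An effect of the receptor or of PPARGD5 also remains open, because each over-expressing group is 1 library and the labels do not describe how Control cells were transfected.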
